A study of Mus musculus with 10 samples.

How the data were processed

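Gene expression was measured on 10 Affymetrix whole-genome mouse oligonucleotide arrays, each hybridized with biotin-labelled cRNA from 1 sample of sorted splenic B cells. The arrays fall into 3 groups: naive B cells of unimmunized Balb/c mice (n = 4), and germinal centre (GC) B cells from 2 lines of mice that carry a transgenic immunoglobulin heavy chain in place of their own rearrangements, called B1-8 (n = 3) and V23 (n = 3). The GC cells were sorted by surface stain as λ+ PNA+ B220+ cells 14 days after immunization with 50 µg of NP-CGG, a hapten coupled to a carrier protein, in alum. The naive cells therefore differ from the GC cells in immunization, in the transgene and in the stain used to sort them, and these cannot be told apart in the comparisons with naive cells. Nothing in the labels says that the replicates are separate animals; where they are not, the p-values measure only the spread between these samples.

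The deposited values are log2 probe set signals, 1 column per array. The authors' notes name GCRMA, without a version, as the processing tool. The values do not have that form: they have no floor and no shared quantiles, and the mean of the unlogged signals after trimming 2% at each end was 500 on every array, which is the form of MAS5 signals scaled to a common target. They were used as deposited, with no further normalization between arrays. Values between −4.29 and 14.9 occurred, and low values carry little order: the median residual SD was 0.889 for genes averaging below log2 6 and 0.118 for genes above log2 10. Arrays give no counts, so the number of arrays and the signal over background limit the precision.

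Of 45101 probe sets, 34958 are assigned to exactly 1 gene symbol, 932 to several and 9211 to none in the annotation used here. For each of 18194 symbols the single-symbol probe set with the highest mean over the 10 arrays was kept, and genes with a log2 value above 4 on at least 3 arrays were tested, which left 17204. Gene identities are given as symbol and probe set; no genome coordinates are given. Of 440 genes in the lists below, 392 were tested; 47 have no probe set of their own symbol alone and were not analysed here.

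Differences between groups were tested with limma 3.58.1 in R 4.3.3: 1 linear model of the 3 group means over all 10 arrays, with empirical Bayes moderation and no intensity trend, two-sided, and Benjamini-Hochberg adjustment within each comparison (threshold 0.05). The comparisons were GC B1-8 with naive, GC V23 with naive, GC B1-8 with GC V23, and the mean of both GC groups with naive. Residual degrees of freedom were 7, with a prior of 1.46. Log2 fold changes are followed by ± their standard error, and group levels by ± the SD.

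There were 21 gene lists and 12 marker lists, fixed with the tests and with the rule for naming genes before the data were examined. The 12 marker lists cover other cell types that the sort could hold, other B cell subsets, sex-linked genes and handling stress. Lists with 5 or more measured genes were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with adjustment over the lists; camera with a correlation estimated from the data and the self-contained test fry were run beside it. Members that pass the test were counted after adjustment over all genes and after adjustment over the list alone. Named genes are the 10 highest and 10 lowest log2 fold changes of GC against naive among genes called in both lines with no overlap between GC and naive arrays. For B1-8 against V23 they are the called genes, filled up by smallest p to 5 per direction. Up to 4 members per list and comparison with the smallest p may also be named, and 13 measured key genes are named whatever their result. Probe sets whose name ends in _x_at, which can share sequence with other genes, were left out of the first 2 parts of the rule.

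The lines' responses were compared by the Pearson correlation of their fold changes across genes, beside simulated groups with no effect and beside fold changes taken from a separate pair of naive arrays for each line, since both comparisons use the same 4 naive arrays. RNA quality was read from the 3′ minus 5′ difference of the Gapdh and Actb control probe sets, with exact permutation tests. The main test was run on simulated data with 200 changed genes: it recovered 48.0%, 48.5% and 49.0% of 2-fold changes in GC B1-8 against naive, GC V23 against naive and GC B1-8 against GC V23, but 12.5%, 12.0% and 0% of 1.5-fold changes. Alternatives covered the filter, the choice of probe set, quantile normalization, median centring, a floor at log2 4, the intensity trend with robust moderation, array weights, a 2-fold minimum, fits of the compared groups alone, the replicate number as a block, and each array left out in turn. Leaving out naive replicates 2 and 4 together, and centring for the list tests, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.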

Results

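The series profiles splenic GC B cells from 2 heavy chain transgenic lines, and naive B cells, on 10 arrays. In both lines λ light chains give B cells that bind the hapten NP, B1-8 with higher affinity than V23 as known from earlier work on these transgenes, so that the comparison of the lines bears on GC B cells that differ in antigen affinity. Array medians were close, at 6.88 ± 0.11 (SD, n = 4) for naive, 6.81 ± 0.04 (n = 3) for B1-8 and 6.75 ± 0.04 (n = 3) for V23 on the log2 scale. Arrays of a group correlated with each other at a mean r, across tested genes, between 0.952 and 0.958. RNA quality differed with the groups: the Actb 3′ minus 5′ difference was 1.46 ± 0.17 in naive, 0.98 ± 0.20 in B1-8 and 0.78 ± 0.08 in V23 samples. The GC minus naive difference was −0.59 (two-sided exact permutation p = 0.0048, the smallest that 210 splits allow; adjusted 0.024 over 10 such tests).

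GC B1-8 B cells differed from naive B cells in 5796 of 17204 genes, 2828 higher and 2968 lower. Kcnn4, a calcium-activated potassium channel, rose by 5.38 ± 0.29 (log2), and S1pr2, the sphingosine phosphate receptor that holds B cells in the GC, rose by 3.88 ± 0.46. Bcl2, which protects naive B cells from death, changed by −3.69 ± 0.19, and Ccr7, the chemokine receptor for the T cell zone, by −4.89 ± 0.55. All 22 measured mitosis genes and 22 of 23 DNA replication genes rose, and 13 of 15 interferon response genes fell. A change of at least 2-fold was found for 1058 higher and 1187 lower genes. With each array centred on its median, the counts were 3392 higher and 2307 lower, because centring moved the median fold change of all genes from 0.05 to 0.15.

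GC V23 B cells differed from naive B cells in 6513 genes, 3127 higher and 3386 lower, with at least 2-fold changes for 1168 and 1546. Kcnn4 rose by 5.13 ± 0.29 and S1pr2 by 3.90 ± 0.46, while Bcl2 changed by −4.07 ± 0.19 and Ccr7 by −4.52 ± 0.55. Again all 22 mitosis genes and 22 of 23 DNA replication genes rose, and 14 of 15 interferon response genes fell. Centring on the median gave 4070 higher and 2517 lower genes, with the median of all genes moving from 0.06 to 0.21.

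For the mean of both GC groups against naive, 3521 genes rose and 3619 fell, 1208 and 1406 of them by at least 2-fold (4437 and 2818 with centring, the median moving from 0.06 to 0.18). Without naive replicates 2 and 4, a choice made after they were seen to stand apart, 3108 rose and 2791 fell. The 10 genes with the highest fitted rise under the naming rule were Gpsm2 (1424895_at), which orients the mitotic spindle, at 6.12 ± 0.78; Gcsam (1420544_at), a GC signalling adaptor, at 5.50 ± 0.62; Mnd1 (1452606_at), a recombination factor, at 5.31 ± 0.28; and Kcnn4, Rgcc, Maged1, Nt5dc2, Lcn2, Timd2 and Hp, between 4.62 and 5.25. Values below log2 4 carry little order, and Gpsm2, Mnd1, Maged1, Nt5dc2, Timd2 and Hp had naive arrays there. With values raised to log2 4 they rose by at least 5.35, 3.73, 3.69, 3.53, 4.57 and 4.25, and Mnd1, Maged1, Nt5dc2 and Hp ranked 26, 29, 36 and 11 among all tested genes. Gpsm2 went from 4.02 ± 2.00 in naive samples (n = 4) to 10.05 ± 0.10 in B1-8 and 10.23 ± 0.33 in V23 samples (n = 3 each). Lcn2, a granule protein of neutrophils, and Hp, haptoglobin, which granulocytes also make, moved with the neutrophil markers described below. The 10 largest fitted falls were those of Gpr34 (1422542_at), a lysophospholipid receptor, at −6.93 ± 0.61; Ly6d (1416930_at), a lymphocyte surface protein, at −6.29 ± 0.20; Tbx3 (1448029_at), a T-box transcription factor, at −6.16 ± 0.22; and Ifi204, Tmem163, Ifi44l, Rtp4, Cobll1, Pml and Pglyrp2, between −5.90 and −5.20. Gpr34, Ifi204, Tmem163, Ifi44l and Pglyrp2 had GC arrays below log2 4, and with values raised to it they fell by at least 5.96, 3.51, 5.22, 5.51 and 3.99, with Ifi204 at rank 62 and Pglyrp2 at rank 40. Ly6d went from 12.98 ± 0.05 in naive samples to 7.06 ± 0.48 in B1-8 and 6.32 ± 0.35 in V23 samples. Of these lower genes, Ifi204, Ifi44l, Rtp4 and Pml are induced by interferons.

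**Figure D1:**
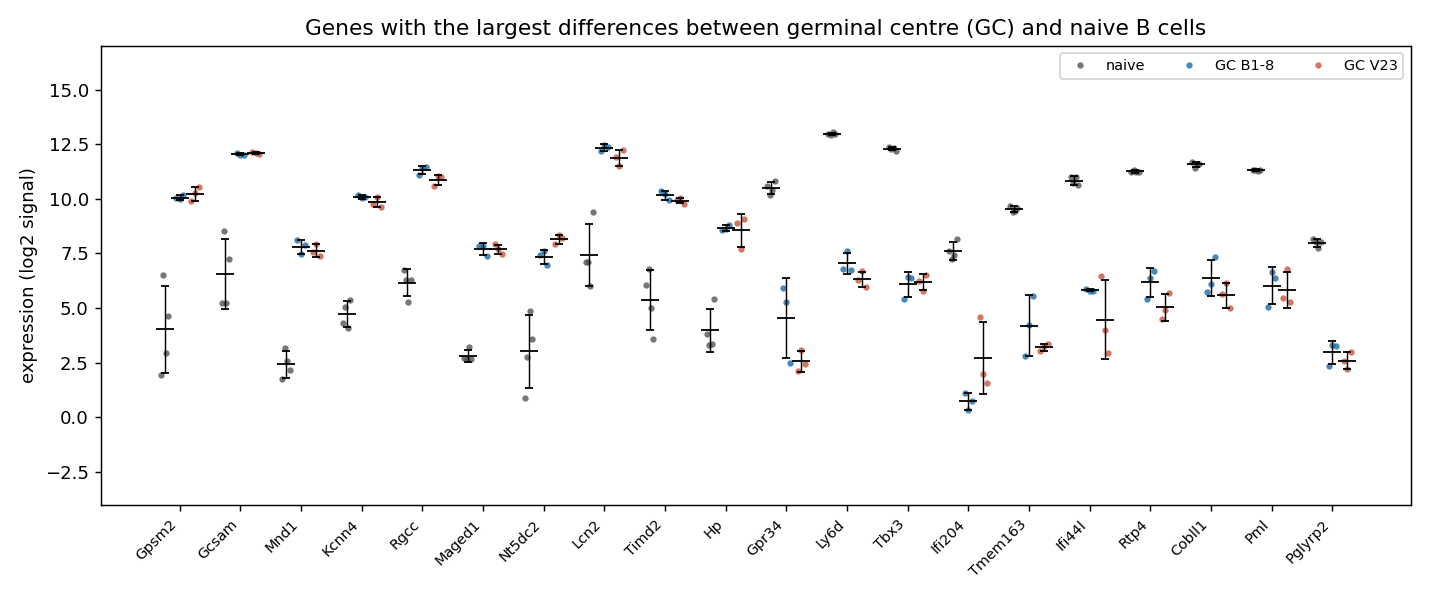
Log2 signal per array (dots) with group mean and SD (bars) for the 10 genes with the largest fitted rise and the 10 with the largest fitted fall in GC against naive B cells. Gpsm2 averaged 4.02 in naive samples and 10.05 in B1-8 samples, and Ly6d averaged 12.98 and 7.06.

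Genes that mark GC B cells rose as a group: 12 of 16 measured members rose and 0 fell (0 also at an unadjusted p under 0.05), and the counts were 12 and 0 adjusted over the list alone. The camera adjusted p was 2.58e-05, and 0.23 with an estimated correlation. Bcl6, the repressor that defines GC B cells, rose by 1.11 ± 0.12, Fas by 1.29 ± 0.16, S1pr2 by 3.89 ± 0.39, the histone methyltransferase Ezh2 by 1.88 ± 0.16 and the transcription factor Mybl1 by 4.22 ± 0.37. Naive replicate 2 lay above the other naive samples in this list, with a mean of 10.82 against 9.50, 9.51 and 10.02, while the 6 GC samples lay between 12.14 and 12.25. Genes of naive follicular B cells moved the other way: 12 of 14 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.17e-05, and adjusted p = 0.198 with an estimated correlation). Bcl2 changed by −3.88 ± 0.16, Ccr7 by −4.71 ± 0.47, the quiescence factor Klf2 by −3.79 ± 0.18 and the egress receptor S1pr1 by −3.05 ± 0.14. Fcer2a, which encodes CD23, changed by −0.44 ± 0.11 (adjusted p = 0.011); its adjusted p was 0.0947 with the mean of its probe sets, 0.0654 with the replicate block and 0.0811 without naive replicates 2 and 4. The 2 that rose were Vpreb3 (1.10 ± 0.07) and Il4ra (0.86 ± 0.10; adjusted p = 0.126 with the mean of its probe sets).

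Proliferation genes rose together. Of 22 mitosis genes all 22 rose, with a median of 3.08 (22 adjusted over the list alone, camera adjusted p = 1.65e-13, and adjusted p = 0.205 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, rose by 3.25 ± 0.21, Aurka by 2.61 ± 0.16 and Tpx2 by 3.48 ± 0.22, although 2 of the other Tpx2 probe sets fell (−1.03 and −0.87). Of 23 DNA replication genes 22 rose and 0 fell, with a median of 1.81 (22 and 0 adjusted over the list alone, camera adjusted p = 2.24e-13, and adjusted p = 0.198 with an estimated correlation). Members included Rrm1, a subunit of ribonucleotide reductase, at 1.94 ± 0.10 and Mcm3, of the replicative helicase, at 1.81 ± 0.12. In both lists naive replicates 2 and 4 were the highest naive samples, at 9.28 and 8.63 in mitosis genes against 7.96 and 8.11 for the others. Dark zone genes, of the GC region where B cells divide, rose in 8 of 10 cases (9 adjusted over the list alone, camera adjusted p = 9.39e-07, and adjusted p = 0.198 with an estimated correlation). Most of that list is mitotic; the DNA polymerase Polh rose by 2.20 ± 0.09, and Cxcr4, the dark zone chemokine receptor, was at 0.57 ± 0.25 (adjusted p = 0.11; 0.0491 without naive replicate 2 and 0.039 without naive replicates 2 and 4). Among 20 genes of hypermutation, switching and DNA repair, 18 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 4.4e-08, and adjusted p = 0.198 with an estimated correlation). Among them were Ung, the uracil glycosylase that acts on deaminated DNA, at 1.62 ± 0.10, Lig1 at 2.50 ± 0.15 and Exo1 at 2.22 ± 0.16. Of 15 histone and chromatin regulators 9 rose and 4 fell (9 and 5 adjusted over the list alone), which did not pass camera (adjusted p = 0.0946). Dnmt1, the maintenance DNA methyltransferase, rose by 1.91 ± 0.11, and Dnmt3a, a de novo methyltransferase, changed by −1.99 ± 0.16.

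**Figure D2:**
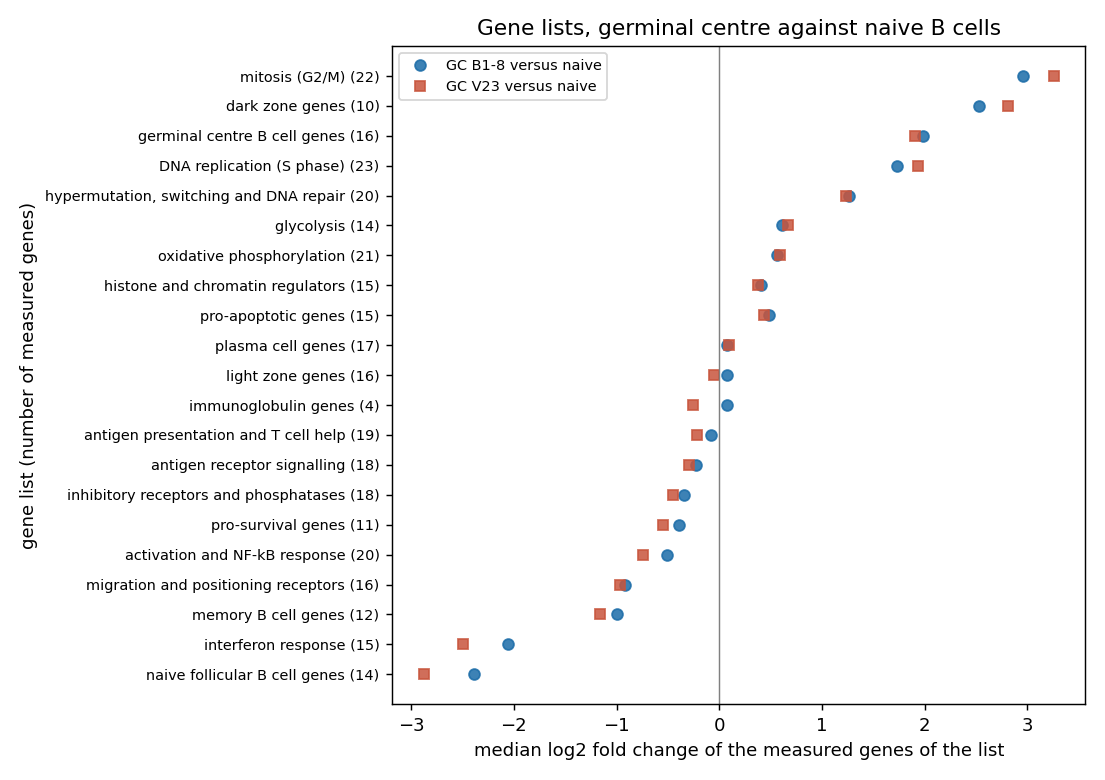
Median log2 fold change of the measured genes of each list (number in brackets) in GC B1-8 (circles) and GC V23 (squares) against naive B cells. Mitosis genes lay at 2.95 and 3.26, and naive follicular genes at −2.39 and −2.88.

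Light zone genes, of the GC region where B cells meet antigen and T cells, went both ways: 6 of 16 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.614). Cd83 rose by 0.38 ± 0.07, the costimulatory ligand Cd86 by 0.56 ± 0.11 and the immediate early gene Egr1 by 1.29 ± 0.09. Myc changed by −0.70 ± 0.15, the cyclin Ccnd2 by −3.06 ± 0.07, and Nr4a1, which antigen receptor signals induce, by −1.95 ± 0.12. The activation and NF-kB list fell in 12 of 20 genes and rose in 4, also adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.228 with an estimated correlation). The list included Irf4 at −1.91 ± 0.11 and the NF-kB inhibitor Nfkbie at −1.25 ± 0.08. Of 18 inhibitory receptors and phosphatases 9 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.198 with an estimated correlation). Ptpn22, a phosphatase, changed by −4.71 ± 0.21 and the receptor Pirb by −2.68 ± 0.14. In B1-8 alone this call ended without B1-8 replicate 3 (adjusted p = 0.0508). Of 18 antigen receptor signalling genes 10 fell and 4 rose (11 and 5 adjusted over the list alone, camera adjusted p = 0.0401, and adjusted p = 0.358 with an estimated correlation). Among them were Malt1 at −1.26 ± 0.11 and the adaptor Grb2 at 0.78 ± 0.08. That call ended with median centring (adjusted p = 0.11), with the mean of each gene's probe sets (0.227), and without naive replicate 2, naive replicate 3, B1-8 replicate 3 or V23 replicate 3 (0.0576 to 0.061).

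Death and survival genes moved apart. Of 11 pro-survival genes 8 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.0269, and adjusted p = 0.198 with an estimated correlation). Members included Cflar, an inhibitor of caspase 8, at −0.90 ± 0.08, but Pim1, a kinase, at 1.52 ± 0.10 and Bcl2l1, which encodes Bcl-xL, at 0.96 ± 0.13. The call ended with the mean of each gene's probe sets (adjusted p = 0.0769), and in B1-8 alone without naive replicate 2 or 3 (0.0542 and 0.0525). Of 15 pro-apoptotic genes 9 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0269, and adjusted p = 0.198 with an estimated correlation). The list included Bak1 at 1.33 ± 0.10, Bad at 1.27 ± 0.11 and Bmf at 0.88 ± 0.08, while Pmaip1, which encodes Noxa, was at −0.88 ± 0.14.

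Receptors for migration fell in 10 of 16 cases and rose in 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00362, and adjusted p = 0.228 with an estimated correlation). Among them were the integrin chains Itga4 at −2.50 ± 0.13 and Itgb7 at −2.89 ± 0.15 and the oxysterol receptor Gpr183 at −2.41 ± 0.16. Of 15 interferon response genes 14 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 2.65e-09, and adjusted p = 0.198 with an estimated correlation). The transcription factor Irf9 changed by −2.20 ± 0.07, Usp18 by −4.59 ± 0.24 and Ifit3 by −3.54 ± 0.26. Oxidative phosphorylation genes rose in 19 of 21 cases and fell in 0 (20 and 0 adjusted over the list alone, camera adjusted p = 7.32e-09, and adjusted p = 0.198 with an estimated correlation). Their median was 0.53, and Sdhb of complex II was at 1.20 ± 0.07. Glycolysis genes rose in 8 of 14 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.205 with an estimated correlation). Members included Tpi1 at 1.51 ± 0.08 and the lactate transporter Slc16a1 at 1.68 ± 0.09. Antigen presentation genes fell in 8 of 19 cases and rose in 4 (8 and 4 adjusted over the list alone, camera adjusted p = 0.158), with Cd274, which encodes PD-L1, at −1.62 ± 0.09 and Icosl, the ligand of ICOS, at −1.75 ± 0.15.

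Lists of the later B cell fates were mixed. Of 17 plasma cell genes 4 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.627). Prdm1, which encodes the plasma cell regulator Blimp-1, was at 0.05 ± 0.23 (adjusted p = 0.9), while Jchain, the joining chain of secreted antibody, rose by 2.44 ± 0.32. Of 12 memory B cell genes 7 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.0973). Hhex changed by −2.78 ± 0.18, and the ectonucleotidase Nt5e, which encodes CD73, rose by 2.18 ± 0.14. Of 4 measured immunoglobulin genes only Ighg3 passed the test (−2.33 ± 0.17; 1 adjusted over the list alone). Marginal zone B cell genes fell in 7 of 9 cases and rose in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 4.38e-05, and adjusted p = 0.198 with an estimated correlation). The list included Cd1d1, the lipid-presenting molecule, at −5.17 ± 0.14. Of 8 B-1 cell genes 3 fell and 0 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.316).

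Markers of other cell types were measured in the same fit. All 8 measured neutrophil markers rose, by a median of 3.22 (8 adjusted over the list alone, camera adjusted p = 0.000163, and adjusted p = 0.243 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, went from 10.77 ± 0.98 in naive (n = 4) to 14.08 ± 0.08 in B1-8 and 13.68 ± 0.25 in V23 samples (n = 3 each), and the granule proteins Ltf and Camp rose by 3.81 ± 0.41 and 4.01 ± 0.43. Naive replicate 4 was the highest naive sample in this list, at 9.26 against 7.35 to 7.80. Macrophage markers were mixed, with 2 of 11 higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.372): Lyz2, which neutrophils also express, rose by 1.83 ± 0.37 and the complement gene C1qb changed by −1.44 ± 0.33 (adjusted p = 0.0647 without naive replicates 2 and 4). T cell markers fell in 2 of 14 cases (1 adjusted over the list alone, and adjusted p = 0.316), NK cell markers in 3 of 6 (3; 0.158), erythroid markers in 2 of 7 (2; 0.497) and platelet markers in 4 of 5 (4; 0.0401, and adjusted p = 0.198 with an estimated correlation). No marker rose in these 4 lists (0 by limma in each). The platelet call ended with quantile normalization (0.0556), with the mean of each gene's probe sets (0.0544), and without naive replicate 3, V23 replicate 1 or V23 replicate 3 (0.0553 to 0.0576). Of 7 dendritic cell markers 2 rose and 2 fell (2 and 2 adjusted over the list alone, and adjusted p = 0.627), and of 8 stromal markers 1 rose and 2 fell (1 and 2 adjusted over the list alone, and adjusted p = 0.394). Heat shock and dissociation genes fell in 6 of 12 cases and rose in 1 (8 and 2 adjusted over the list alone, and adjusted p = 0.0667), with Jun at −1.22 ± 0.14. Naive replicate 4 stood apart here, with a list mean of 8.92 inside the GC range of 8.78 to 9.01, while the other naive samples lay between 9.75 and 10.06. Of 4 sex-linked genes 0 passed by limma, and 0 at an unadjusted p under 0.05; Xist lay at 13.65 ± 0.10 in naive, 13.47 ± 0.20 in B1-8 and 13.25 ± 0.28 in V23 samples.

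**Figure D3:**
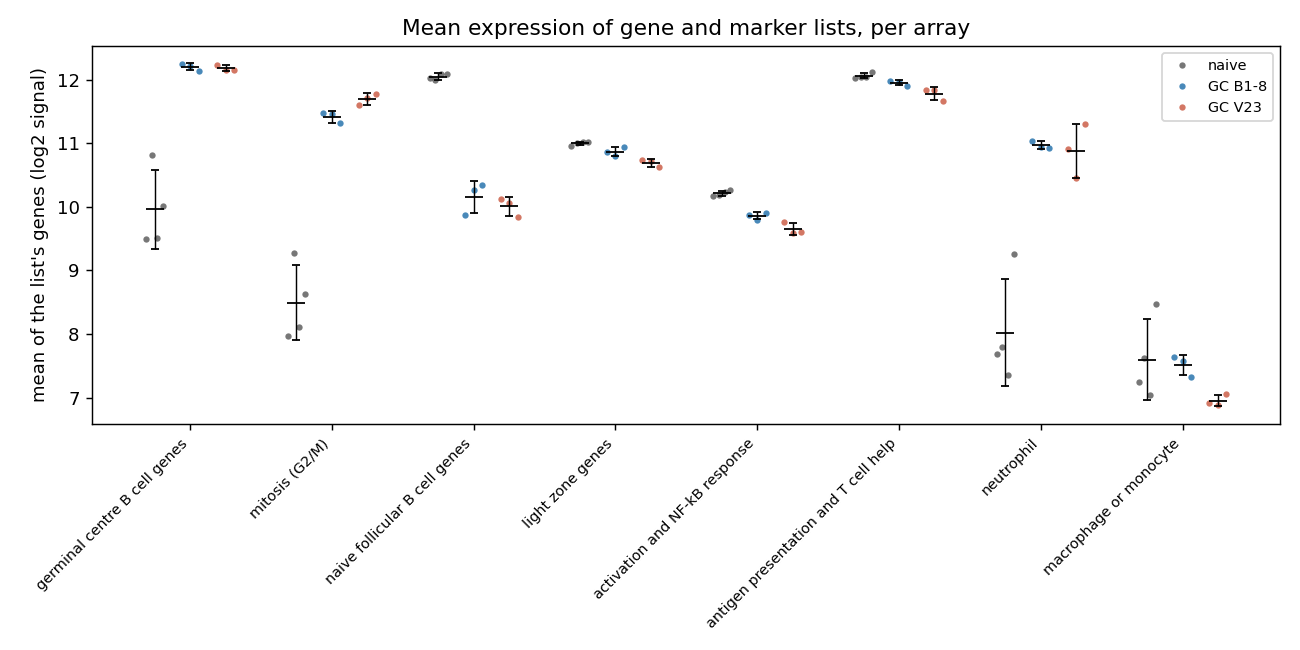
Mean log2 signal of the genes of 8 lists on each array (dots), with group mean and SD (bars), for naive, GC B1-8 and GC V23 samples. Naive replicate 2 stands at 10.82 for GC genes, and naive replicate 4 at 9.26 for neutrophil markers.

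The lines' responses were then set side by side. Of the called genes, 2490 rose and 2673 fell in both lines, and 1 (A4gnt, 0.43 in B1-8 and −0.42 in V23) went opposite ways; 632 were called in B1-8 alone and 1349 in V23 alone, which does not show that those genes differ between the lines. The fold changes correlated across genes at r = 0.886, where genes are not independent replicates. Both comparisons use the same naive arrays, and simulated groups with no effect gave r = 0.428. With a separate pair of naive arrays for each line, r was 0.726 to 0.748. The covariance was 0.814 against 0.0791 in simulated groups, and the shared direction held for 84.9% of genes against 64.1%.

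**Figure D4:**
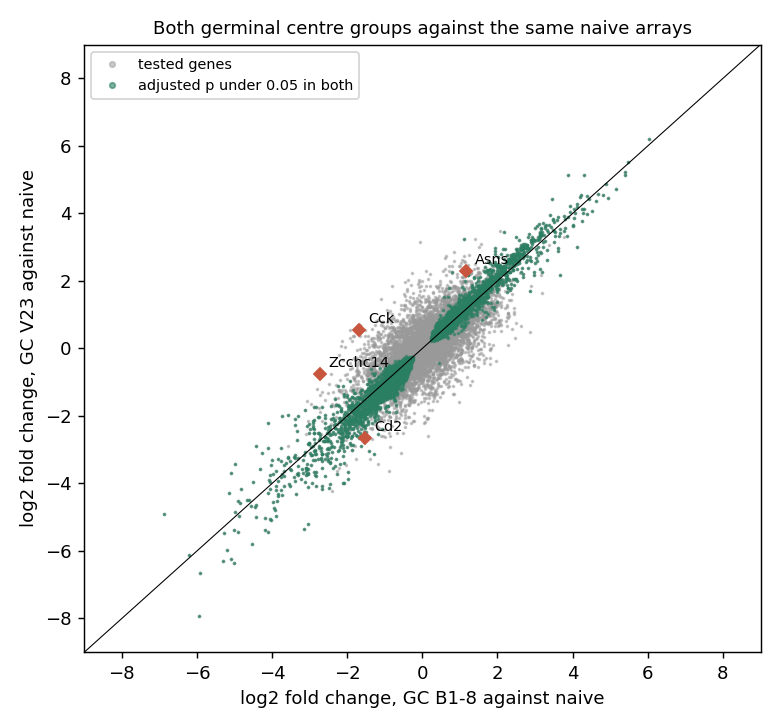
Log2 fold change of every tested gene in GC V23 against naive (vertical axis) and GC B1-8 against naive (horizontal axis); green points passed in both, and the line marks equal changes. The correlation across genes was 0.886, and the 4 marked genes passed the main test between the lines.

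GC B1-8 and GC V23 cells differed in 4 of 17204 genes, 1 higher and 3 lower in B1-8, with 1328 genes at an unadjusted p under 0.05. Cd2 (1418770_at), an adhesion molecule of lymphocytes, was higher in B1-8 by 1.15 ± 0.12 (adjusted p = 0.0369), at 10.36 ± 0.18 against 9.22 ± 0.14 in V23 and 11.88 ± 0.05 in naive samples. Asns (1451095_at), asparagine synthetase, was lower in B1-8 (−1.14 ± 0.10, adjusted p = 0.0369), at 10.08 ± 0.05 against 11.22 ± 0.12 in V23 and 8.93 ± 0.11 in naive samples, and its other probe set gave −1.34. Cck (1419473_a_at), the hormone cholecystokinin, differed by −2.24 ± 0.23 (adjusted p = 0.037) and Zcchc14 (1418168_at), a zinc finger protein, by −1.97 ± 0.21 (adjusted p = 0.046). Both lay below log2 4 in B1-8, at 3.23 and 3.39, where values carry little order: with values raised to log2 4 they differed by −1.47 and −1.36 and did not pass (adjusted p = 0.0996 and 0.0914). A further Zcchc14 probe set gave −0.37 (adjusted p = 0.944). The arrays of the lines did not overlap for any of these 4 genes; over all tested genes they did not overlap for 2357, or 13.7%, where chance gives 10%. Next by p, without passing in the main fit, came A4gnt (0.86 ± 0.11), Ak7 (2.24 ± 0.27), Plbd1 (0.83 ± 0.11) and Sfxn4 (1.88 ± 0.26) on the higher side, and Nanog (−2.15 ± 0.33) and AY074887 (−1.40 ± 0.22) on the lower. Over all alternatives Sfxn4 ran from 1.11 to 2.13 and Nanog from −2.31 to −1.39. The lowest limma adjusted p there was 0.0369 for Ak7, 0.00238 for Plbd1 and 0.0242 for Nanog, while A4gnt, Sfxn4 and AY074887 never passed. The 4 main calls rest on the pooled spread. Without any 1 of the 4 naive arrays limma called 0 genes (1167 to 1335 at an unadjusted p under 0.05), with the same fold changes. Without V23 replicate 2 it called 9 higher and 2 lower, 2 of these 11 among the 4. It called 0 genes without B1-8 replicate 1 or 2 or V23 replicate 1 (1197 to 1671 unadjusted), 1 lower gene without B1-8 replicate 3, which was not among the 4, and 1 in each direction without V23 replicate 3, 1 of them among the 4. The adjusted p over all alternatives ran from 0.00022 to 0.461 for Cd2 and for Asns.

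**Figure D5:**
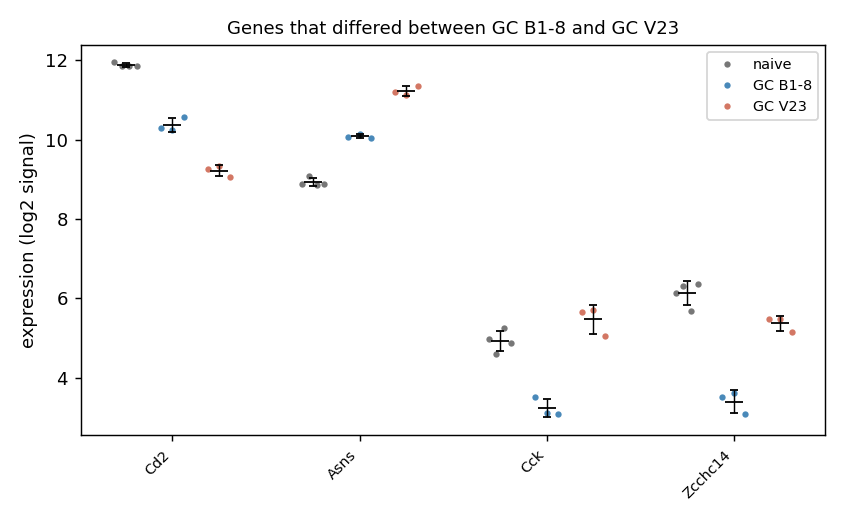
Log2 signal per array (dots) with group mean and SD (bars) for the 4 genes that passed the main test of GC B1-8 against GC V23. Cck and Zcchc14 did not pass with values raised to log2 4. Asns averaged 10.08 in B1-8 and 11.22 in V23 samples, and Cd2 10.36 and 9.22.

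As groups, genes of division lay lower and genes of activation higher in B1-8 than in V23, by small amounts. Genes that rose in GC cells, as division genes did, tended to lie lower in B1-8 in general. For genes above log2 8 the slope of the line difference on the GC change was −0.097. The lists were not tested against that tendency, so a difference particular to division cannot be read from them. All 22 mitosis genes were on the lower side in B1-8, with a median of −0.29 (camera adjusted p = 0.00393, and adjusted p = 0.727 with an estimated correlation). So were 21 of 23 DNA replication genes, with a median of −0.17 (camera adjusted p = 0.0093, and adjusted p = 0.727 with an estimated correlation). All 16 light zone genes were on the higher side, with a median of 0.16 (camera adjusted p = 0.00191, and adjusted p = 0.299 with an estimated correlation), though 15 with quantile normalization and 14 with centring. So were 17 of 20 activation and NF-kB genes, median 0.21 (0.000812, and adjusted p = 0.346 with an estimated correlation). Among them were Nfkbie at 0.45 ± 0.10 and Egr3 at 0.40 ± 0.14. The inhibitory receptors were higher in 16 of 18 cases, median 0.15 (0.00191, and adjusted p = 0.28 with an estimated correlation). Members included Cd72 at 0.64 ± 0.12. Antigen presentation genes were higher in 18 of 19 cases, median 0.16 (0.000812, and adjusted p = 0.523 with an estimated correlation). The list included H2-Oa, a modulator of peptide loading, at 0.40 ± 0.11. Pro-survival genes had a median of 0.14 (0.0379, and adjusted p = 0.346 with an estimated correlation), and that call ended with centring (0.0765), with the mean of each gene's probe sets (0.103), with the replicate block (0.0676) and without naive replicates 2 and 4 (0.0536). Without V23 replicate 3 the medians were 0.10 for light zone, 0.13 for activation and 0.08 for antigen presentation genes (adjusted p from 0.0169 to 0.0442). Without B1-8 replicate 3 they were −0.07 for DNA replication and 0.09 for pro-survival genes, which no longer passed (0.268 and 0.147). T cell markers (median 0.48; 0.0493, and adjusted p = 0.673 with an estimated correlation) and macrophage markers (0.40; 0.00773, and adjusted p = 0.673 with an estimated correlation) also lay higher in B1-8, in which C1qb was at 1.13 ± 0.42.

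No single member of any list passed the test of B1-8 against V23 over all genes (0 by limma). Adjusted over the list alone, 3 immunoglobulin genes were higher in B1-8. They were Igha (1.38 ± 0.46, but 0.88 without B1-8 replicate 1), Ighg3 (0.62 ± 0.21, but 0.40 without V23 replicate 3) and Ighm (0.32 ± 0.12). The Igha probe set, 1429381_x_at, is of the kind that can share sequence with other genes. The lines carry different heavy chain transgenes, and whether that bears on these genes was not tested. Adjusted over their own lists alone, Nfatc1 (0.52 ± 0.11), Cd72, Nfkbie and Casp9 (0.36 ± 0.08) were also higher in B1-8, and Bmf was lower (−0.39 ± 0.11). At an unadjusted p under 0.05 the lists held 0 to 4 genes in either direction. Fry passed for the inhibitory receptors (adjusted p = 0.0313) and for none of the other 8 groups, with 0.0634 for light zone and for activation genes. The DNA replication call ended without B1-8 replicate 3 (adjusted p = 0.268) or V23 replicate 2 (0.0935). The pro-survival and T cell calls ended without B1-8 replicate 2 or 3 or V23 replicate 2 or 3 (0.0611 to 0.147 and 0.129 to 0.214; T cell also without naive replicate 2, 0.0555, and with quantile normalization, 0.0962), and the macrophage call without B1-8 replicate 2 (0.0506). The GC list (median 0.04, camera adjusted p = 0.705), the interferon list (0.21; 0.0706), the antigen receptor signalling list (0.08; 0.111) and the neutrophil markers (0.31; 0.853) did not pass in this comparison.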

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

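Among the tests below, those of macrophages, of cycling cells, of naive cells in the B1-8 samples and of array scaling were chosen only after the result was seen. The arrays were also regrouped. Of 35 splits of the naive and B1-8 arrays only the real one, 1 split, called as many genes (5796, highest other 22). The same held for 1 of 35 for V23 (6513, highest other 16). For both GC groups together it was 1 of 100 drawn splits (7140, highest other 6). The other splits mix GC and naive arrays, so the GC difference enlarges their residual spread. They place the real grouping first, but do not give the count that chance alone would call. For B1-8 against V23, 2 of 10 splits called 4 or more genes (real 4, highest other 4), and 10 splits are too few for a share under 0.05.

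Neutrophil markers were higher in GC samples, although the cells were sorted as λ+ PNA+ B220+ with dead cells excluded. The macrophage markers C1qb, C1qc and Csf1r were all lower in GC samples, the highest at −0.77, so these 3 did not rise with the neutrophil markers. They were picked from the macrophage list after the values were seen, and Lyz2 of that list rose. The test therefore cannot decide on macrophages or monocytes in the GC samples. Granulocytes among the GC cells stay open: of 18 measured granulocyte genes outside the marker list, 10 (55.6%) rose, with Chil3 at 3.62 and Olfm4 at 3.11, but 3 fell, namely Trem1, Pglyrp1 and Cybb, the last of which B cells also express. This share lay between the bounds set beforehand, and the most abundant markers were near the top of the range in all 6 GC samples (S100a8 at 14.08 in B1-8 and 13.68 in V23, 10.77 in naive). Immunization differs along with the GC sort, and expression of these genes by the GC B cells themselves was not tested.

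Naive replicate 2 stood above the other naive samples in genes of GC B cells, 11 of the 12 called GC genes being highest in it among the naive samples. Of these 12 genes, 11 lie outside the cell cycle and chromatin lists, and they exceeded the highest other naive sample by a median of 1.21. The excess was therefore not limited to cell cycle genes. It was first seen in these same genes, so the test cannot weigh cycling cells of another kind independently. GC B cells within that sample may be the source and stay open. For the 12 called GC genes, the excess of naive replicate 2 over the other naive samples was taken as a share of the GC rise over them, in unlogged signal. The median share was 16.3% (quartiles 14.2 and 21.7). Of 69 other GC-high genes 57 were highest in naive replicate 2, but 40 (58.0%) had a share within 2 times of that, between the bounds set beforehand. The median share of the 69 was 10.3% (quartiles 5.53 and 14.3), below that of the genes in which the excess was first seen. For 58 genes above log2 10 in the other naive samples and below −3 in GC against naive, naive replicate 2 differed by a median of −0.11. The design places this sample with the other naive samples and gives no factor that sets it apart, and beyond these 2 tests of other cells in the sample no biological explanation was tested. The labels name no stain that would remove such cells from the naive sort.

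GC V23 samples lay farther from naive samples than GC B1-8 samples did: of 1430 genes above log2 8 that changed at least 2-fold, 80.7% changed more in V23, and the slope of the line difference on the GC change was −0.097, the largest of 10 splits (largest other 0.0708, in size). A larger share of naive cells in B1-8 samples is argued against as the cause for the mitosis genes. Genes nearly lost in GC cells allow 1.62% (quartiles 0.417 and 2.66) where the mitosis genes need 19.4% (14.5 and 21.9). The nearly lost genes were chosen by their mean fall in both lines, which favours genes low in B1-8. The share that the whole slope would need was not computed. Array scaling is argued against as the whole cause, since the slope was −0.083 after quantile normalization. The RNA quality difference stays open, with an Actb 3′ minus 5′ difference 0.20 higher in B1-8 (exact permutation p = 0.2, where 3 against 3 cannot go below 0.1). A difference between the lines, such as their antigen affinity, also stays open and untested, and 10 splits are too few to exclude chance.

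Of 82 values tested in the 4 naive samples, 11 had 1 sample far from the other 3; chance gives about 1 in 20. Naive replicate 4 had an array median of 7.04 (others 6.81 to 6.84), an antigen presentation mean of 12.13 (12.03 to 12.05), an NK cell mean of 8.35 (7.65 to 7.76) and Klf2 at 11.74 (12.07 to 12.11). Naive replicate 2 had a hypermutation and repair mean of 9.81 (9.44 to 9.50), a chromatin regulator mean of 11.27 (11.06 to 11.07) and Asns at 9.08 (8.85 to 8.89). Naive replicate 3 had a pro-apoptotic mean of 8.95 (9.12 to 9.15), Maged1 at 3.21 (2.66 to 2.71) and Pml at 11.26 (11.33 to 11.34). Naive replicate 1 had Cd2 at 11.95 (11.85 to 11.86). The Maged1 values lie below log2 4, where values carry little order.

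The GC responses of the lines differed by the limma test for Cd2 (1.15, B1-8 minus V23), Asns (−1.14), Cck (−2.24) and Zcchc14 (−1.97). By camera with its preset correlation they differed for light zone (median 0.16), inhibitory receptor (0.15), activation (0.21), pro-survival (0.14), antigen presentation (0.16), T cell (0.48) and macrophage genes (0.40), and for DNA replication (−0.17) and mitosis genes (−0.29), none of which held with an estimated correlation (adjusted p from 0.28 to 0.727). These lists were not tested against the general tendency of V23 to lie farther from naive. Among 8129 tested probe sets without a gene name in the annotation, 494 were higher and 1701 lower in GC than in naive samples.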

How the results depend on the processing

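Leaving out naive replicates 2 and 4, and centring for the list tests, were chosen only after the result was seen; the other alternatives were planned. No list that passed camera changed direction under the alternatives run, nor did the called genes among the top, key and list member genes of the naming rule, each with its chosen probe set or the mean of its probe sets. Which of the higher and lower counts was larger did change: against naive, more genes were lower in each comparison, but more were higher with quantile normalization (3212 and 2677 for B1-8, 3748 and 2949 for V23, 4113 and 3179 for both), with centring (3392 and 2307, 4070 and 2517, 4437 and 2818), with the replicate block, without naive replicates 2 and 4 (2503 and 2295, 2847 and 2671, 3108 and 2791) and without naive replicate 4 (2877 and 2731, 3176 and 3130, 3548 and 3299), and for both with array weights (3776 and 3749) and with only the compared groups (3593 and 3577). Every probe set was also taken as its own feature (41235 tested), which allows larger totals. That gave 5185 higher and 6598 lower for B1-8 against naive, 5811 and 8009 for V23, and 6760 and 8612 for both. The share higher among the calls also moved, from 49.3% in the main fit to 44.0% for both. The cause of that move was not tested. Probe sets of a gene did not always agree: of called genes with another called probe set, 221 of 1951 for B1-8, 329 of 2346 for V23 and 408 of 2650 for both had one called in the opposite direction. A 2-fold minimum gave 1058 and 1187, 1168 and 1546, and 1208 and 1406, as its construction implies. Under the other alternatives these counts stayed within 1.5 times, with leave-one-out ranges of 2233 to 2877 higher and 2495 to 2968 lower for B1-8, 2587 to 3176 and 2947 to 3348 for V23, and 3044 to 3548 and 3190 to 3556 for both. With the replicate number as a block they were 2561 and 2503, 2919 and 2906, and 3303 and 3126. Only the naive group has a replicate 4, so the block fits that array exactly and takes it out of these comparisons. The median fold changes of all genes with the block equalled those without naive replicate 4 (0.090, 0.103 and 0.099). The block is therefore not separate evidence on which count was larger. Replicate numbers gave no sign of pairing. In 2 of 9 same-number pairs the second group's array was the best match of the first group's array. The reverse was not checked, and residual correlations ran from −0.02 to 0.07.

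The 4 genes of B1-8 against V23 depended on the setting. The count higher in B1-8 (1) was 0 with the mean of probe sets, with median centring, with the replicate block, without naive replicates 2 and 4 and with only the compared groups, 2 with values raised to log2 4 and 12 with trend and robust moderation. The count lower (3) was 0 with the mean of probe sets, with the block, without naive replicates 2 and 4 and with only the compared groups, 1 with every probe set and 5 with trend and robust moderation. Of the 17 genes called with trend and robust moderation 2 were among the 4, and of the 4 called with values raised to log2 4, 2 were. Among these settings, where limma called 0 in both directions, 1089 to 1286 genes had an unadjusted p under 0.05. Leave-one-out gave 0 to 9 higher and 0 to 2 lower. Fewer arrays leave fewer residual degrees of freedom. This applies to leave-one-out, to leaving out naive replicates 2 and 4 and to the fit of the compared groups alone. The replicate block also uses up residual degrees of freedom. For the other settings the cause was not tested. The correlation of the responses moved from 0.886 to a mean of 0.738 with the naive arrays split. The split removes the shared controls, but it also leaves each line 2 naive arrays in place of 4, which adds noise. The parts of the move were not told apart.

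For the 33 top and key genes of GC against naive, 490 of 495 alternative values kept their side of the threshold, 3 lost it (Fcer2a) and 2 gained it (Cxcr4); for the 10 top genes of B1-8 against V23, 106 of 148 kept it, 38 lost it and 4 gained it. For the 114 other list members with the smallest p in GC against naive, 2403 of 2504 values kept their side, 75 (19 genes) lost it and 26 (10 genes) gained it, among them Xist with quantile normalization (adjusted p = 0.0306), with trend and robust moderation (0.0292) and without V23 replicate 1 (0.0258), and Ighm with the mean of its probe sets. For the 122 members of B1-8 against V23, 2673 of 2675 kept it and 2 gained it (Nfatc1 and Cd72, with trend and robust moderation). Apart from the estimated correlation, list calls kept their direction and side in 294 of 306 cases for both GC groups, 268 of 272 for B1-8, 297 of 306 for V23 and 128 of 153 for B1-8 against V23; with it, all 18, 16, 18 and 9 calls ended. Low signal limits genes below log2 6, of which 14.0% were called in GC against naive, against 65.4% above log2 10.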

Other observations

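Of the tests in this part, camera on the wider amino acid list and the random lists matched to the synthetases were chosen only after the result was seen, and so were some members of the amino acid list. Camera on the other synthetases and the random lists matched to the amino acid list were set before their values were seen. Asns was among the 4 genes that passed the main test between the lines. Most genes of a list of amino acid synthesis, import, tRNA charging and stress response lay the same way. The list also holds 10 genes of stress response and regulation, such as Ddit3, Trib3, Atf4 and Vldlr. Without Asns, 23 of its 26 measured genes were lower in B1-8 than in V23, by a median of −0.27, with 12 lower and 0 higher at an unadjusted p under 0.05 and 0 past limma's adjusted threshold. The amino acid transporter Slc7a5 was at −1.09 ± 0.20, the folate enzyme Shmt2 at −0.52 ± 0.10, the alanyl-tRNA synthetase Aars at −0.61 ± 0.15, and Phgdh, of serine synthesis, at −0.26 ± 0.08. Vldlr, Slc7a11 and Ddit4 lay higher in B1-8, at 0.71, 0.60 and 0.36. Since members were chosen partly from these values, neither the list's camera p (0.00209 unadjusted, with an estimated correlation) nor its comparison with 10000 matched random lists (0% as low) can support the pattern.

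A hypothesis is that GC V23 cells may express tRNA synthetases at a higher level than GC B1-8 cells. Of 13 other cytosolic tRNA synthetases, not looked at before, 10 were lower in B1-8, by a median of −0.20 (camera unadjusted p = 1.06e-05; 0.00231 with an estimated correlation). Of the 13, 5 were lower and 0 higher at an unadjusted p under 0.05, Iars at −0.36 ± 0.10 and Rars at −0.26 ± 0.08 among them, and 0 passed limma's adjusted threshold. Vars, Hars and Qars lay higher in B1-8, at 0.10, 0.03 and 0.01. For the general tendency of V23 to lie farther from naive, 10000 random lists were matched to these 13 genes on level and on GC change. Their medians centred on −0.036 and 0% were as low, the lowest being −0.194 against −0.199. The random lists draw each gene singly, whereas synthetases may vary together, so the 0% overstates the evidence. The general tendency therefore stays open as a cause. The hypothesis was found on the same 6 GC samples that test it, and the RNA quality difference between the lines stays open.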
